A study of Mus musculus with 6 samples.

How the data were processed

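Total RNA of kidneys from male BALB/c mice at 8 weeks of age was sequenced, with 1 library at each of 6 zeitgeber times (ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20) under a light/dark cycle. Per the labels, kidneys were flash frozen on dry ice, RNA was extracted with Trizol and a column kit, and strand-specific libraries were made with Agilent's SureSelect kit. The submitters' processing notes name bcl2fastq 2.20 and the build mm9. The aligner and the tool that estimated the levels are not given in the sources used here.

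The authors deposited 1 table of FPKM values with 1 column per library, in which each line is an Ensembl transcript and not a gene, per the file headers. It holds 128603 transcripts of 51803 gene symbols. The transcript length in bases is also deposited there and, per the file headers, is a property of the transcript; it entered only the check for length trends. The loci in the table were compared with GENCODE mouse release M21 on GRCm38. Of 127971 transcripts matched by identifier, 126203 (98.62%) lay inside the locus that the table gives, so positions are given on GRCm38 from GENCODE although the notes name mm9.

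FPKM values hold no read counts, so the depth of the libraries is unknown and no counting interval can be given. The low values were examined for steps of whole reads in symbols with a single transcript. Among the lowest 10% of the products of FPKM and length, 99.8% to 100.0% of the values differed from one another, so whole reads were not recovered. The sum of FPKM per library lay between 534448 and 577493, and rescaling by the median of ratios moved no library by more than 0.041 on the log2 scale.

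For each symbol the transcript with the highest mean FPKM over the 6 libraries was used, a rule fixed before the data were examined for a table with several lines per symbol. This transcript held a median of 89.9% of the FPKM of its symbol among the genes tested. The alternative, the sum of all transcripts of a symbol, was also fixed beforehand. Genes with a mean of at least 1 FPKM (12195) were tested on log2(FPKM + 1), so fold changes understate those of low genes.

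The labels give 1 sample per time, so time entered as a continuous covariate. A cosine and a sine term of 24 h were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with 3 residual degrees of freedom per gene, and the moderated F test was adjusted by Benjamini-Hochberg over all genes tested (threshold 0.05). The residual spread holds the differences between mice and the departure from a cosine together, and the p-values measure a time course of single libraries. Amplitude is given on the log2 scale from mean to peak, with its SE from the moderated residual variance. A wave of 12 h was fitted in the same way. The 6 libraries can be placed on a circle in 60 distinct orders, and the fit was repeated in each, with 0.0167 as the smallest permutation p. For the 12 h wave there are 15 distinct pairings.

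Before the data were examined, 40 gene lists (clock, stress and hormone responses, renal transport, metabolism and markers of cell types) were fixed, and 36 had at least 2 genes tested. For each list a one-sided Fisher exact test compared members past the threshold with all other genes tested, adjusted over the lists, and the mean share of variance taken by the cosine was set against the 60 orders by an exact permutation test. Lists are also described by the median over members of log2(FPKM + 1) minus the gene mean. Sgk1, Cdkn1a and several transport genes are in more than 1 list, so the lists are not independent.

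Genes named in the text follow a rule fixed before the data were examined: every core clock gene tested, the 4 genes with the largest amplitude past the threshold and a mean of at least 5 FPKM in each of 6 windows of 4 h, up to 4 genes with the smallest limma p in each list, and, for cell type and handling lists, the genes with the largest range. Since fewer than 12 genes passed over all windows, the rule's fallback took the 4 genes with the smallest limma p among those with a mean of at least 5 FPKM in each window, with unnamed gene models left out. From the 4 of each list the text prints 1 to 4, and the values of some genes that the rule names are not reported here. Aqp3, Cd2ap, Fabp4, Krt19, the 3 small RNA genes of the 12 h fit and the genes listed for the summed transcripts were named after their values were seen.

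The fit was tested on simulated data, with waves of known amplitude added to 200 of 12195 genes in 6 libraries over 20 runs. At adjusted p under 0.05 it found 47.7% of waves of amplitude 0.5, 87.2% of amplitude 1 and 97.3% of amplitude 2, and called 7.75 of 11995 flat genes per run on average. The simulated noise was normal and independent between genes, and 200 planted waves make the adjusted threshold easier to reach. These shares therefore do not give the power in the real data, where 2 genes passed and Dbp (amplitude 2.38) had a limma adjusted p of 0.0507. Alternatives were a pseudocount of 0.1, no filter and a minimum mean of 5 FPKM, median-of-ratios and quantile normalization, limma without trend and with robust moderation, ordinary least squares, permutation per gene, a threshold of 0.1, summed transcripts and the omission of each time in turn. Unadjusted member counts, removal of each library's trend on transcript length and GC content, and some uses of summed transcripts were added after the first results were seen. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.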

Results

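Kidney RNA was profiled in male BALB/c mice, an inbred albino laboratory strain, at 8 weeks of age, at 6 times of the light/dark cycle. Time is given as zeitgeber time (ZT), counted in hours from lights on. The libraries were taken at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, with 1 library at each time, so no value below has a spread between replicates and the error of each rhythm comes from the departure of the 6 libraries from a cosine curve. Levels are FPKM (fragments scaled to transcript length and to the mapped fragments of the library) of the most abundant transcript of each gene, and 12195 genes with a mean of at least 1 FPKM were tested. The median level of these genes lay between 6.93 FPKM (ZT4) and 7.35 FPKM (ZT20). Transcripts of the mitochondrial genome took 22.2% of all FPKM at ZT20 and 28.6% at ZT4. The number of reads behind each library is unknown, because the values are normalised.

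The series asks which kidney genes follow a daily rhythm, and the genes of the circadian clock showed the clearest one. Npas2, which encodes a partner of BMAL1 in the activating arm of the clock, was at 6.45 FPKM at ZT0 and 6.20 FPKM at ZT20 and at 0.186 FPKM at ZT12. Nr1d1, which encodes the clock repressor REV-ERBα, was highest at ZT4 with 39.0 FPKM and lowest at ZT20 with 1.14 FPKM. These were the 2 genes of 12195 that passed the 24 h test (limma, moderated F test, Benjamini-Hochberg adjusted p = 0.0433 for both). The fitted amplitude of Npas2 was 1.52 ± 0.08 (SE, log2 scale, n = 6 libraries) with a peak at ZT22.4 ± 0.196 h, and that of Nr1d1 was 2.25 ± 0.13 with a peak at ZT5.56 ± 0.218 h. Npas2 (ENSMUSG00000026077) lies on the forward strand of chromosome 1 from 39193731 to 39363236, and Nr1d1 (ENSMUSG00000020889) on the reverse strand of chromosome 11 from 98767932 to 98775333 (GRCm38).

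Of the 19 genes of the core clock list, 18 were tested. The 2 genes above passed over all genes tested, 14 passed when adjusted over the list alone, and 14 had an unadjusted p under 0.05. The share of passing genes in this list exceeded that among all other genes (one-sided Fisher exact test, Benjamini-Hochberg adjusted p = 7.41e-05 over 36 lists). That call was lost with log2(FPKM + 0.1), no filter, quantile normalization, no trend, ordinary least squares and the length and GC trend removed. It was also lost without ZT0, ZT4, ZT8, ZT12 or ZT16, and kept without ZT20. With members counted at unadjusted p the list was called (Fisher adjusted p = 1.92e-06), and this call was kept under all 16 alternatives. The genes peaked in sequence around the day. Arntl, which encodes BMAL1, had its fitted peak at ZT21.1 and went from 0.078 FPKM at ZT8 to 8.77 FPKM at ZT20 (limma adjusted p = 0.0507). Dbp, a transcription factor driven by the clock, went from 1.41 FPKM at ZT0 to 50 FPKM at ZT8, with the largest fitted amplitude of the list at 2.38 ± 0.18 (adjusted p = 0.0507). Its relative Tef peaked at ZT8.69, between 14.1 and 37.2 FPKM, and Nr1d2, the paralog of Nr1d1, at ZT8.64, between 6.25 and 44.6 FPKM. Ciart, a repressor of the clock, was at 4.48 FPKM at ZT8 and at 0.048 FPKM at ZT0. Among the period and cryptochrome repressors, Per3 peaked at ZT9.97, Cry2 at ZT13.7, Per2 at ZT14.1 and Cry1 at ZT16.7. Per2 went from 0.941 FPKM at ZT0 to 11.8 FPKM at ZT16, and Cry1 from 0.614 FPKM at ZT4 to 9.29 FPKM at ZT20. Hlf, a relative of Dbp, had its fitted peak at ZT13.3. Nfil3, a repressor that shares binding sites with DBP, had its fitted peak at ZT19.7 and went from 0.597 FPKM at ZT8 to 13.5 FPKM at ZT20. Clock, Bhlhe40, Per1 and Rora did not reach an unadjusted limma p of 0.05 (exact permutation test over the 60 circular orders, p = 0.25, 0.333, 0.417 and 0.3). With all transcripts summed, Per1, whose single transcript held 43.9% of the gene, had an amplitude of 0.68 with a peak at ZT12.0 (limma adjusted p = 0.0985), and Clock an adjusted p of 0.228, both with an unadjusted p under 0.05. By the transcripts used here Clock stayed between 5.12 and 8.37 FPKM, Rora between 6.49 and 9.25 FPKM, Bhlhe40 between 19.9 and 49.1 FPKM and Per1 between 0.687 and 2.06 FPKM.

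**Figure D1:**
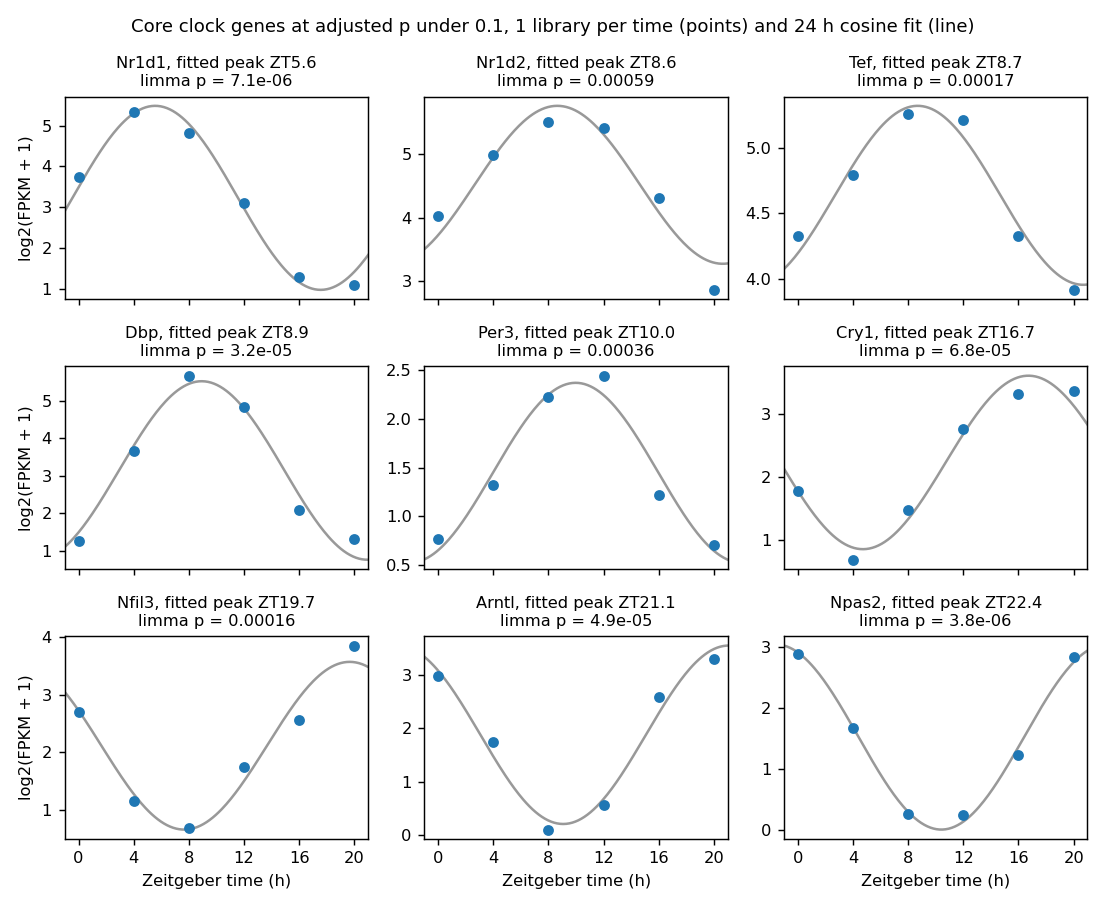
Level of the 9 core clock genes with an adjusted p under 0.1 (y axis, log2 of FPKM + 1, separate scale in each panel) against zeitgeber time in hours (x axis), with 1 library per time as points and the 24 h cosine fit as a line. Panels are ordered by fitted peak from Nr1d1 (ZT5.56) to Npas2 (ZT22.4), and the limma p printed in each panel is unadjusted.

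The mean share of variance that the 24 h cosine took in the core clock genes was 0.848 in the order given by the labels. The highest value in the other 59 circular orders of the libraries was 0.747, so the exact permutation p was 0.0167, the smallest that 60 orders can give. Without ZT0, ZT4, ZT8, ZT12 or ZT16, 0 genes passed the adjusted threshold (limma), while between 1444 and 2173 genes had an unadjusted p under 0.05. Without ZT20, 2 genes passed, Nr1d1 and Dbp.

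Beyond the clock, the genes with the smallest limma p among those with a mean of at least 5 FPKM in each window of the day did not pass the adjusted threshold. With highest levels late in the dark phase or at lights on were Ppard, a nuclear receptor for fatty acids, which was at 19.1 FPKM at ZT20 and 3.68 FPKM at ZT8, and Slc16a1, the lactate and pyruvate transporter MCT1, which was at 28.0 FPKM at ZT0 and 4.45 FPKM at ZT8. Slc25a22, a mitochondrial glutamate carrier, and Tbc1d14 completed that window, with fitted amplitudes of 0.65 ± 0.06 and 0.69 ± 0.07. In the window around ZT4, next to Nr1d1, stood Pi4ka, a lipid kinase, with 56.7 FPKM at ZT4 and 29.2 FPKM at ZT20, Tmem86a with 42.8 FPKM at ZT8 and 9.49 FPKM at ZT16, and Sgtb with 7.70 FPKM at ZT4 and 3.50 FPKM at ZT16. Around ZT8, next to Dbp, stood the kinase Prkd3 at 13.9 FPKM at ZT4 and 3.48 FPKM at ZT20, and Slc9a3, the sodium-proton exchanger NHE3 of the proximal tubule, at 39.5 FPKM at ZT8 and 21.9 FPKM at ZT20. The adjusted p of these genes lay between 0.0507 (Ppard, Slc16a1) and 0.0912 (Tmem86a, Sgtb) by limma. The transcripts taken for Tbc1d14 and Prkd3 held 37.0% and 38.1% of the FPKM of their genes, and with all transcripts summed the amplitudes were 0.20 and 0.49 (limma adjusted p = 0.253 and 0.101).

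In the window around ZT12, Prnp, the prion protein gene, was at 114 FPKM at ZT12 and 58.1 FPKM at ZT0, and Coq10b, which encodes a coenzyme Q binding protein, at 73.7 FPKM at ZT8 and 22.6 FPKM at ZT0. The neighbouring paralogs Nat8f6 and Nat8f5 were at 59.1 and 85.1 FPKM at ZT12, and reads shared between them make their separate levels uncertain. Around ZT16, Sgk1, the kinase that raises sodium channel activity under aldosterone, was at 25.5 FPKM at ZT16 and 6.81 FPKM at ZT4, with an amplitude of 0.95 ± 0.08 and a peak at ZT16.4. Slc5a3, the myo-inositol transporter, was at 48.7 FPKM at ZT16 and 21.5 FPKM at ZT4, on a locus that it shares with an overlapping gene, and Baiap2 at 8.97 FPKM at ZT16 and 3.12 FPKM at ZT4. Around ZT20, the tubulin gene Tuba4a was at 49.1 FPKM at ZT20 and 22.3 FPKM at ZT4, Llgl2, a cell polarity gene, at 26.2 FPKM at ZT20 and 13.8 FPKM at ZT8, and Ypel2 at 10.5 FPKM at ZT0 and 2.37 FPKM at ZT8. The haemoglobin genes Hbb-bs and Hba-a1 fell in the same windows and are described with the blood markers. Adjusted p in these windows lay between 0.0507 (Prnp, Nat8f6, Sgk1, Tuba4a) and 0.0769 (Ypel2) by limma. The single transcript taken for Tuba4a held 34.9% of the gene's FPKM and that for Baiap2 44.1%, and with all transcripts summed their adjusted p were 0.191 and 0.235.

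Across the transcriptome, 2195 of 12195 genes (18.0%) had an unadjusted limma p under 0.05 for a 24 h wave, against 610 expected from that threshold, and 98 had an adjusted p under 0.1. The median amplitude of the 2195 genes was 0.29, and 267 of them had an amplitude of at least 0.5. In the other 59 circular orders of the same libraries the count at unadjusted p under 0.05 lay between 141 and 1928 genes. At most 1 gene had an adjusted p under 0.05 there. The order with 1928 genes was the labelled one with only ZT4 and ZT8 exchanged, so it keeps much of any 24 h wave and is no reference for chance. In the labelled order the count fell to 1049 genes without the ZT20 library and to 1444 without the ZT16 library, the only omissions that moved it by over 1.5 times. Summing all transcripts of a gene in place of taking the most abundant one gave 36 genes at adjusted p under 0.05, among them Npas2, Nr1d1, Dbp, Arntl, Cry1, Per3, Tef, Nfil3, Sgk1 and Avpr1a, with at most 1 gene in any other order.

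**Figure D2:**
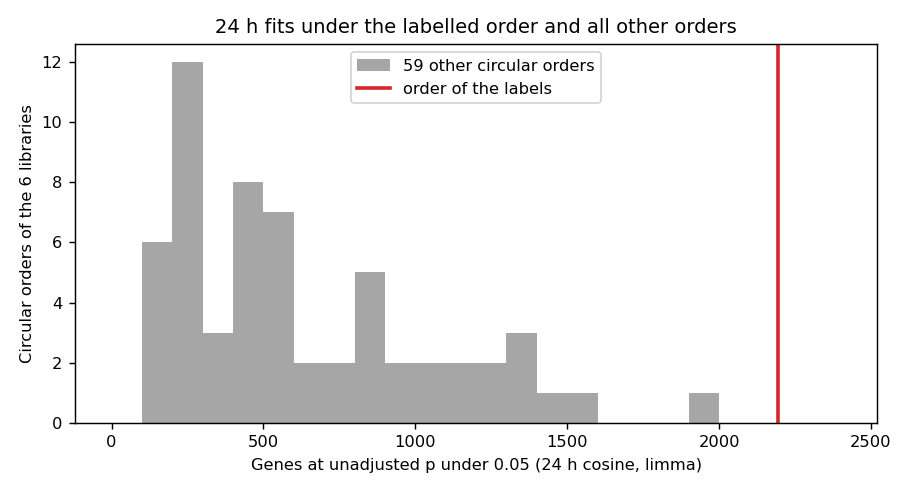
Number of genes at unadjusted p under 0.05 in the 24 h limma fit (x axis) for the 59 other circular orders of the 6 libraries (grey bars, y axis: number of orders) and for the order of the labels (red line). The labelled order gives 2195 genes, and the highest other order, which only exchanges ZT4 and ZT8, gives 1928.

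Many fitted peaks lay at ZT16 and ZT20, times of 1 library each, and these 2 libraries also stood apart on the first principal component (-0.431 and -0.643, against 0.013 to 0.477 for the others, 31.5% of the variance). Of the 2195 genes at unadjusted p under 0.05, 566 (25.8%) peaked in the 4 h window around ZT20 and 557 (25.4%) in that around ZT16, while 152 (6.9%) peaked around ZT12 and 203 (9.2%) around ZT0. The windows around ZT4 and ZT8 held 341 and 376 genes. The ZT16 and ZT20 windows held 51.2% of these genes and 44.4% of all genes tested. They held 41.8% of the 98 genes at adjusted p under 0.1 and 38.9% of the 36 genes at adjusted p under 0.05 with summed transcripts. The 95% binomial intervals of these 2 shares (31.9% to 52.2% and 23.1% to 56.5%) include 44.4%, so the stricter sets show no excess. The window around ZT0 held 21.4% and 27.8% of them. Of the 2 genes that passed the adjusted threshold, Npas2 peaked in the window around ZT0 and Nr1d1 in that around ZT4, so 0 of 2 lay between ZT14 and ZT22, which allows a share of up to 84.2% (exact 95% binomial interval).

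**Figure D3:**
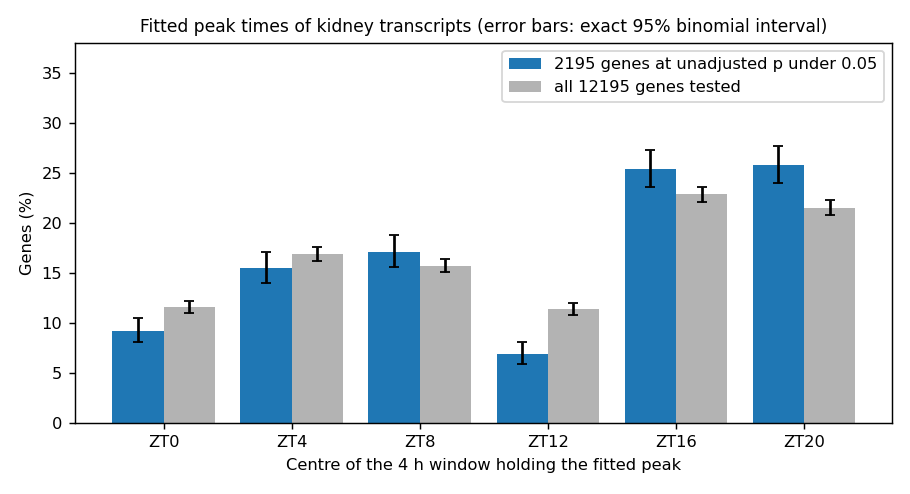
Share of genes (y axis, percent) whose fitted 24 h peak lies in each 4 h window (x axis, centre of the window), for the 2195 genes at unadjusted p under 0.05 (blue) and all 12195 genes tested (grey). Error bars are exact 95% binomial intervals, which treat genes as independent, and the ZT16 and ZT20 windows hold 25.4% and 25.8% of the first set.

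For the gene lists fixed before the data were examined, only the core clock list was called with members past the adjusted threshold. Since 2 genes passed over all genes, a second criterion was chosen after that count was seen, with members counted at an unadjusted limma p under 0.05 and the Fisher exact test adjusted over the 36 lists. It called 9 lists: the core clock, heat shock, endoplasmic reticulum chaperones, immediate early genes, water transport and concentration, xenobiotic metabolism, cholesterol biosynthesis, podocyte markers and blood markers. With the mean share of variance taken by the cosine, 15 lists reached the smallest p that the 60 orders allow (0.0167, adjusted p = 0.04, exact permutation test). These were the core clock, glucocorticoid response, immediate early genes, sodium, acid-base and amino acid transport, xenobiotic metabolism, fatty acid oxidation, cholesterol biosynthesis, renin-angiotensin and kinin genes, hypoxia, ribosomal proteins, and the markers of S1 and S2 proximal tubule, principal cells and intercalated cells. The labelled order also had the highest median share over all genes tested (0.564, against 0.548 in the next order), so this rank does not set a list apart from other genes. Below, a list is said to be called when it passed the Fisher test. That test counts the members of a list as independent genes. Members regulated together can carry 1 signal of a single library several times, so its p-values can be too small. The member counts below use the unadjusted criterion unless the adjustment over the list alone is named.

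Heat shock chaperones were high at ZT16. All 16 tested genes had their highest level in the ZT16 library, and the median over members stood 0.91 above the gene mean at ZT16 and 0.23 above it at ZT20 (log2 scale), with values between -0.37 and -0.14 at the other times. Hsp90aa1 was at 214 FPKM at ZT16 and 57.0 FPKM at ZT4, the small heat shock protein gene Hspb1 at 21.8 and 3.20 FPKM, and the co-chaperone genes Dnajb1 and Bag3 at 25.1 and 17.0 FPKM at ZT16 and 8.32 and 8.58 FPKM at their lowest. The transcript taken for Hsp90aa1 held 55.4% of its gene. With all transcripts summed its amplitude was 0.594 in place of 0.855 (limma adjusted p = 0.25). Of the 16 genes, 9 had an unadjusted p under 0.05 (Fisher adjusted p = 0.00592) and 5 passed when adjusted over the list alone. The count was 14 without ZT12, and 6 without ZT16 or ZT20, where the call was kept (Fisher adjusted p = 0.0249 and 0.00902). The call was lost without ZT8 (6 members, adjusted p = 0.0953), with median-of-ratios size factors (7, 0.0576), by ordinary least squares (1, 1.0) and with the trend on transcript length and GC content removed (6, 0.187). The cosine took less of the variance than in another order of the libraries (mean 0.655 against 0.669).

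The cold-inducible RNA binding protein genes ran the other way. Cirbp was at 29.4 FPKM at ZT0, 5.29 FPKM at ZT16 and 7.24 FPKM at ZT20. Rbm3 differed less, at 17.9 FPKM at ZT0, 28.6 FPKM at ZT12, 16.5 FPKM at ZT16 and 13.7 FPKM at ZT20. Both passed when adjusted over the list alone (limma adjusted p = 0.0186 for each), with p = 0.167 for Cirbp and 0.117 for Rbm3 in the exact permutation test. The list itself was not called (Fisher adjusted p = 0.0833), though it was with no filter (0.0316). Its 2 members at unadjusted p under 0.05 became 0 without ZT20 and 1 without ZT8 or ZT16. The Rbm3 transcript held 33.7% of its gene, and with all transcripts summed the amplitude was 0.36 in place of 0.43.

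Chaperones of the endoplasmic reticulum were high at ZT16 and ZT20, where the median over members stood 0.49 and 0.32 above the gene mean. Sdf2l1 was at 24.4 FPKM at ZT16 and 4.12 FPKM at ZT8, and the calcium binding chaperone gene Calr at 455 FPKM at ZT20 and 247 FPKM at ZT12. Xbp1, a transcription factor of the unfolded protein response, was at 63.5 FPKM at ZT16 and 32.6 FPKM at ZT0. Herpud1, which acts in the degradation of endoplasmic reticulum proteins, peaked earlier, at ZT12.8, between 63.8 and 113 FPKM. Of 15 genes, 9 had an unadjusted p under 0.05 (Fisher adjusted p = 0.00411) and 2, Herpud1 and Sdf2l1, passed when adjusted over the list alone. Leaving out ZT4, ZT8, ZT16 or ZT20 ended the call (6, 6, 3 and 3 members, adjusted p between 0.0863 and 0.358), as did size factors, ordinary least squares and removal of the length and GC trend (6, 1 and 5 members). Of the 60 orders, 10 gave as high a mean share of variance, the real one included.

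Immediate early genes, which respond within minutes to stimulation, were higher from ZT12 to ZT20 than from ZT0 to ZT8. The median over members stood between 0.11 and 0.23 above the gene mean at ZT12, ZT16 and ZT20 and between -0.22 and -0.15 at the earlier times. Klf2 was at 3.56 FPKM at ZT16 and 1.28 FPKM at ZT4, Jun at 13.6 FPKM at ZT12 and 7.61 FPKM at ZT4, and Cyr61 at 13.7 FPKM at ZT16 and 5.75 FPKM at ZT8, while Zfp36 peaked earlier, at ZT10.7. Of 14 genes, 8 had an unadjusted p under 0.05 (Fisher adjusted p = 0.00837) and 7 passed when adjusted over the list alone. Without ZT16 the count was 5 (adjusted p = 0.0511), and the call was also lost by ordinary least squares (0.0626) and with the length and GC trend removed (0.0711).

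Genes that respond to glucocorticoids included 4 of 13 that passed when adjusted over the list alone, Sgk1, Cdkn1a, Tsc22d3 and Ddit4. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, was at 48.3 FPKM at ZT12 and 7.34 FPKM at ZT0, and Ddit4 at 11.6 FPKM at ZT16 and 6.01 FPKM at ZT0. Cdkn1a, an inhibitor of the cell cycle, peaked at ZT22.2 and went from 1.02 FPKM at ZT8 to 4.33 FPKM at ZT0. The list as a whole was not called (6 members, adjusted p = 0.0658), though it was without ZT0, ZT16 or ZT20 (adjusted p = 0.0411, 0.00208 and 0.0172).

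In the water transport and concentration list, several genes were highest at ZT16 or ZT20, but not all. Aqp2, the vasopressin-regulated water channel, was at 181 FPKM at ZT16 and 82.3 FPKM at ZT4, and the vasopressin V2 receptor gene Avpr2 at 9.10 FPKM at ZT20 and 5.43 FPKM at ZT8. Avpr1a, the V1a receptor gene, was at 6.56 FPKM at ZT20 and 1.89 FPKM at ZT8, with an amplitude of 0.75 ± 0.05, a peak at ZT21.5 and an adjusted p of 0.0507 over all genes (limma). Aqp3, a basolateral water channel, was at 94.0 FPKM at ZT12 and 68.2 FPKM at ZT20. Of 17 genes, 8 had an unadjusted p under 0.05 (Fisher adjusted p = 0.0254) and 6 passed when adjusted over the list alone. Without ZT0 or ZT12 the count was 6 and the call was lost (adjusted p = 0.108 and 0.0702), as it was with genes of at least 5 FPKM (0.246), by ordinary least squares (0.19) and with the length and GC trend removed (0.0711). The mean share of variance was 0.669, against 0.692 in another order.

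Of 23 sodium, chloride and potassium transport genes, 4 had an unadjusted p under 0.05 (Fisher adjusted p = 0.687), and Sgk1 and Slc9a3 passed when adjusted over the list alone. Scnn1a, a subunit of the epithelial sodium channel, was at 20.5 FPKM at ZT12 and 13.8 FPKM at ZT4, and Atp1b1, a subunit of the sodium pump, at 1330 FPKM at ZT12 and 938 FPKM at ZT20. The other transport lists were not called by the Fisher test. Slc4a4, the basolateral bicarbonate cotransporter, was at 160 FPKM at ZT4 and 105 FPKM at ZT20 and was the 1 acid-base gene of 17 to pass when adjusted over the list alone. Of the amino acid transport genes, 5 of 15 did so, with Slc7a8 at 24.7 FPKM at ZT20 and 10.5 FPKM at ZT12 and Slc6a19, the neutral amino acid transporter B0AT1, at 59.3 FPKM at ZT8 and 23.97 FPKM at ZT16. None of the calcium, phosphate and vitamin D genes (0 of 18), the glucose genes (0 of 15) or the organic ion and drug transport genes (0 of 17) passed when adjusted over the list alone by limma, with 7, 6 and 6 members at an unadjusted p under 0.05. In these lists Cyp27b1, which makes active vitamin D, was at 2.16 FPKM at ZT8 and 0.465 FPKM at ZT20, the glucose transporter gene Slc2a2 at 41.5 FPKM at ZT4 and 29.6 FPKM at ZT20, and Slco1a1 at 324 FPKM at ZT4 and 120 FPKM at ZT20. Leaving out 1 time brought a call for calcium (without ZT4, Fisher adjusted p = 0.029), acid-base (without ZT0, 0.0173), organic ion (without ZT16, 0.0124) and amino acid transport (without ZT4, ZT8, ZT16 or ZT20, 0.019 to 0.0386). Other omissions lowered the count, to 3 for calcium (without ZT8), 3 for acid-base (without ZT16 or ZT20), and 2 for glucose and 0 for organic ion transport (without ZT20). The amino acid list stayed uncalled under 7 of 16 alternatives, and was called with median-of-ratios factors (0.0477), quantile normalization (0.0119), robust moderation (0.0433), summed transcripts (0.0421) and no filter (0.024). The calcium list was also called with median-of-ratios factors (0.0466), summed transcripts (0.014) and no filter (0.0203), acid-base with log2(FPKM + 0.1) (0.0269) and no filter (0.0258), and the glucose and organic ion lists with no filter (0.0479 and 0.0163).

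Cholesterol synthesis genes were highest at ZT20, where the median over members stood 0.21 above the gene mean, against -0.14 at ZT8. Insig1, which restrains the activation of sterol-regulated transcription factors, was at 32.4 FPKM at ZT20 and 16.1 FPKM at ZT8, and Msmo1, a sterol methyl oxidase of the pathway, at 17.8 FPKM at ZT20 and 11.1 FPKM at ZT8. Of 18 genes, 11 had an unadjusted p under 0.05 (Fisher adjusted p = 0.00103) and 7 passed when adjusted over the list alone. The mean share of variance was 0.716, against at most 0.624 in the other orders. The call was lost without ZT8 (7 members, adjusted p = 0.0726) and by ordinary least squares (adjusted p = 0.0626).

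Of 23 xenobiotic metabolism genes, 10 had an unadjusted p under 0.05 (Fisher adjusted p = 0.021) and 8 passed when adjusted over the list alone, with peaks at different times. Cyp2e1 was at 1158 FPKM at ZT4 and 650 FPKM at ZT20, and Por, the electron donor of microsomal P450 enzymes, at 107 FPKM at ZT8 and 69.7 FPKM at ZT20. Ces1d, a carboxylesterase gene, was at 153 FPKM at ZT16 and 81.1 FPKM at ZT8, and Cyp2d26 at 54.7 FPKM at ZT20. Leaving out any 1 time kept the call, with 6 members without ZT20 and 8 to 10 otherwise, and ordinary least squares (adjusted p = 0.19) and removal of the length and GC trend (adjusted p = 0.0711) ended it.

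Among other metabolic and response lists, none of which the Fisher test called, Nampt and Nmrk1, both in NAD synthesis, passed when adjusted over their list of 15 alone, Nampt at 59.6 FPKM at ZT12 and 36.3 FPKM at ZT4 and Nmrk1 at 19.4 FPKM at ZT12 and 6.58 FPKM at ZT0. In the hypoxia list of 12, Ndrg1 was at 1576 FPKM at ZT0 and 308 FPKM at ZT8, with an amplitude of 1.14 ± 0.15, and Bnip3 was at 106 FPKM at ZT12. These 2 passed when adjusted over the list alone. In the renin-angiotensin and kinin list 4 of 7 did so. Of these, Agtr1a, the angiotensin receptor gene, was at 25.04 FPKM at ZT4 and 15.95 FPKM at ZT16, Ace at 45.5 FPKM at ZT4 and 28.0 FPKM at ZT20, and Ptger3 at 26.7 FPKM at ZT20 and 15.96 FPKM at ZT4. That list was called without ZT8, ZT12 or ZT16 (adjusted p = 0.0236, 0.0406 and 0.019), with genes of at least 5 FPKM (0.0166), with summed transcripts (0.0151) and with no filter (0.0479). For fatty acid oxidation 0 of 23 genes passed by limma over the list alone (6 at an unadjusted p under 0.05), with Cpt1a at 124 FPKM at ZT8 and 71.4 FPKM at ZT20. Without ZT4 this list was called (11 members, Fisher adjusted p = 0.00663), but it had 3 members without ZT12 and 2 without ZT20. In the cell cycle list of 11, Cdkn1a and Wee1 passed when adjusted over the list alone, Wee1 with 6.87 FPKM at ZT12 and 1.82 FPKM at ZT4, and with no filter the list was called (10 members, adjusted p = 0.000389). Interferon and antigen presentation genes had 0 of 13 past that adjustment (4 unadjusted), with Cd74 at 74.97 FPKM at ZT20 and 46.9 FPKM at ZT4. Ribosomal protein genes had 0 of 22 (6 unadjusted) and respiratory chain genes 0 of 20 (1 unadjusted), and both were lowest at ZT4, with a median of -0.32 and -0.18 from the gene mean. Rpl18 was at 78.7 FPKM at ZT4 and 125 FPKM at ZT20, and Atp5g1 at 106 FPKM at ZT4 and 179 FPKM at ZT16. The ribosomal list was called without ZT8 (14 members, Fisher adjusted p = 1.77e-05), but had 2 members without ZT4 and 0 without ZT12, ZT16 or ZT20. In the ZT4 library short transcripts as a whole were low, with a median of -0.18 in the 10% of genes with the shortest transcripts.

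**Figure D4:**
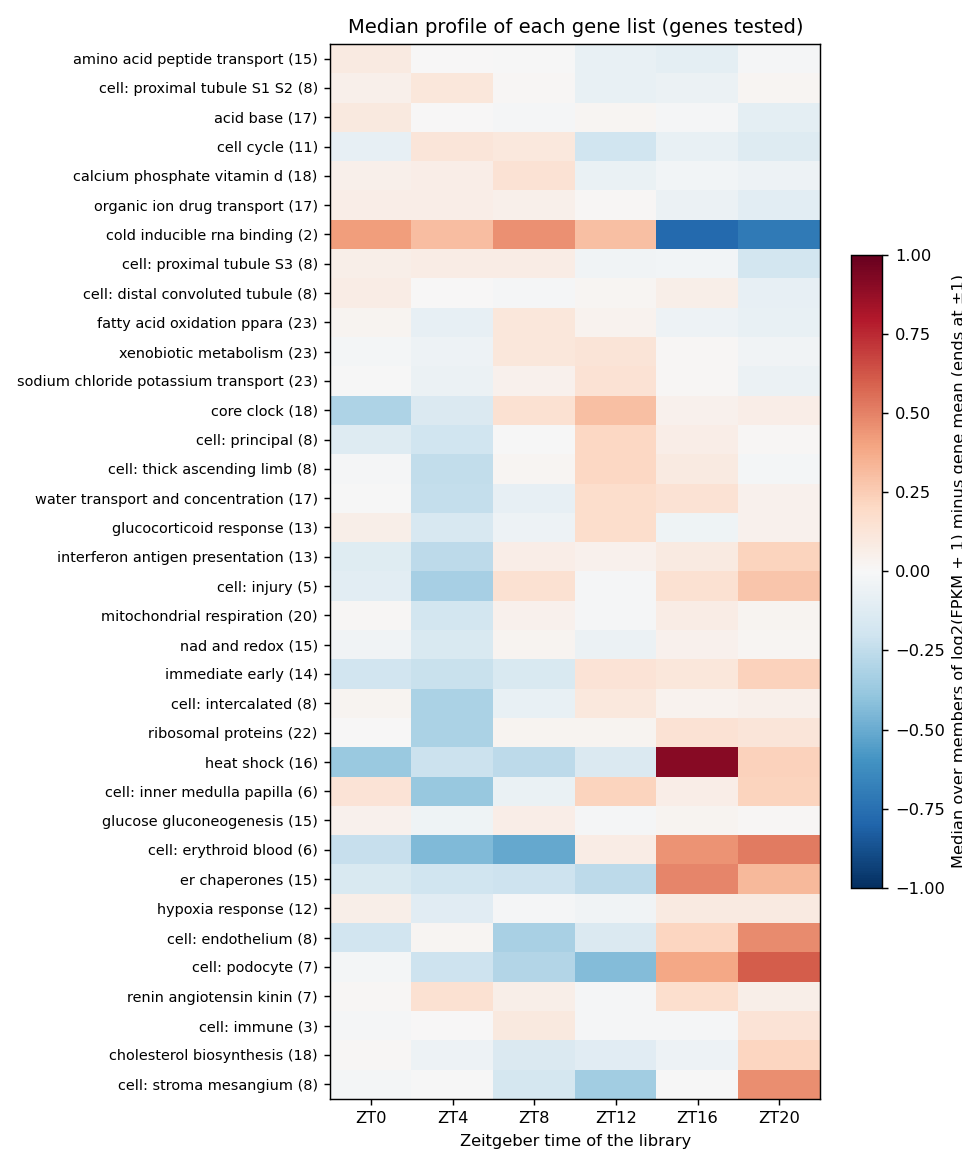
Median over the tested members of log2 (FPKM + 1) minus the gene mean (colour, ends at 1 and -1) for each of the 36 gene lists (y axis, number of genes tested in brackets) in each library (x axis, zeitgeber time), ordered by the peak of the fitted cosine. Heat shock genes reach 0.91 at ZT16, and podocyte markers 0.61 at ZT20.

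Markers of cell types were compared across the same libraries, since whole kidney mixes many of them. Podocyte markers were highest at ZT20, with a median of 0.61 above the gene mean, and lowest at ZT12, at -0.44. Nphs1, which encodes nephrin, was at 2.43 FPKM at ZT20 and 0.622 FPKM at ZT12, Synpo at 4.35 and 1.44 FPKM, and Podxl at 33.6 FPKM at ZT20 and 14.5 FPKM at ZT12. Of 7 genes, 5 had an unadjusted p under 0.05 (Fisher adjusted p = 0.0172) and 3 passed when adjusted over the list alone. Without ZT20 the count was 0 (adjusted p = 1.0), and without ZT0, ZT4 or ZT8 it was 4, 3 and 4 (adjusted p = 0.0517, 0.22 and 0.0695). The call was also lost with log2(FPKM + 0.1) (0.0715), genes of at least 5 FPKM (0.198), quantile normalization (0.214), ordinary least squares (1.0) and the length and GC trend removed (0.132), so it was kept under 7 of 16 alternatives, and the mean share of variance was 0.688, against 0.784 in another order. At ZT16 the podocyte median stood 0.39 above the gene mean. Endothelial and stromal markers were also highest at ZT20, with medians of 0.48 and 0.47 above the gene mean, and at ZT16 stood at 0.22 and -0.01. The endothelial genes Plvap and Flt1 were at 48.9 and 5.83 FPKM at ZT20 and 24.1 and 2.28 FPKM at ZT8, and the smooth muscle genes Tagln and Acta2 at 10.7 and 7.001 FPKM at ZT20 and 3.83 and 2.64 FPKM at their lowest. Neither list was called (3 of 8 members each, Fisher adjusted p = 0.231), but both were without ZT0 (6 members, 0.00348), and the endothelial list also without ZT4 (6 members, 0.00663). Without ZT16 or ZT20 each list had 1 member, as had the endothelial list without ZT8.

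Blood markers were high at ZT16 and ZT20. Hbb-bs was at 204 FPKM at ZT16 and 79.1 FPKM at ZT8, Hbb-bt at 23.7 and 7.24 FPKM, and Hba-a1 at 71.3 FPKM at ZT20 and 26.6 FPKM at ZT8, where reads shared between the near-identical globin copies leave each separate level uncertain. Of 6 genes, 4 had an unadjusted p under 0.05 (Fisher adjusted p = 0.0461) and 4 passed when adjusted over the list alone, and leaving out any 1 time kept the call. Hbb-bs, Hbb-bt and Hba-a1 were among these 4, and the Fisher test counts such copies as independent genes, so the call can rest on 1 signal counted more than once. The mean share of variance was 0.753, against 0.863 in another order, and 6 of the 60 orders gave as high a value, the real one included. The list was not called by ordinary least squares (3 members, adjusted p = 0.19) or with the length and GC trend removed (3 members, 0.201).

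Tubule markers moved less. Those of the S1 and S2 proximal tubule stayed within -0.07 and 0.12 of the gene mean in the median, with Gatm, the first enzyme of creatine synthesis, at 52.3 FPKM at ZT20 and 23.6 FPKM at ZT12 and Slc5a12 at 149 FPKM at ZT4 and 82.98 FPKM at ZT20. For the S3 segment the median was lowest at ZT20 (-0.18), with Acy3 at 749 FPKM. Thick ascending limb and principal cell markers were highest at ZT12, with medians of 0.20 and 0.21, and in the first Cldn10 was at 62.4 FPKM at ZT12 and 121 FPKM at ZT0. Intercalated cell and inner medulla markers were lowest at ZT4 (-0.32 and -0.38), where the inner medulla gene Cryab was at 7.43 FPKM, against 33.6 FPKM at ZT16. In the distal convoluted tubule list Slc12a3, the thiazide-sensitive cotransporter gene, was at 64.1 FPKM at ZT0 and 42.3 FPKM at ZT16 (exact permutation test, p = 0.383). That transcript held 39.2% of the gene, and with all transcripts summed the amplitude was 0.31 with a peak at ZT0.823 and an unadjusted p under 0.05 (limma adjusted p = 0.166). None of these 7 tubule lists was called by the Fisher test (adjusted p between 0.0893 and 0.737), while S3 was without ZT16 (0.0277) and thick ascending limb without ZT0 (0.0198), and the S1 and S2 and principal cell lists were with no filter (4 members and 0.024 each). Immune markers had 0 of 3 genes at an unadjusted p under 0.05, with Lyz2 between 21.2 and 28.0 FPKM, and injury markers 1 of 5, Spp1, at 384 FPKM at ZT20 and 238 FPKM at ZT4. Havcr1, a marker of tubule injury, was at 29.8 FPKM at ZT8 and 12.5 FPKM at ZT4. Urothelial, adipocyte, adrenal and skeletal muscle lists had fewer than 2 genes at a mean of 1 FPKM or more. The highest mean among their genes was 49.6 FPKM for Fabp4, which endothelial cells also express, and 1.37 FPKM for Krt19 among the rest.

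A wave of 12 h was fitted to the same libraries, with times 12 h apart serving as repeats. It called 3 genes at adjusted p under 0.05 (limma), the small nuclear RNA genes Gm25709 and Gm26427 and the small nucleolar RNA gene Gm24523. Each was listed at 0 FPKM in 4 of the 6 libraries. Gm25709 was at 78.0 FPKM at ZT0 and 52.5 FPKM at ZT12, Gm24523 at 13.03 FPKM at ZT8 and 9.08 FPKM at ZT20, and Gm26427 at 53.5 FPKM at ZT8 and 147 FPKM at ZT20. At unadjusted p under 0.05 there were 207 genes, against 610 expected from that threshold and up to 1987 in another pairing of the libraries. The pairing with 1987 genes took neighbouring times as repeats (ZT0 with ZT4, ZT8 with ZT12, ZT16 with ZT20). A 24 h wave can raise the count of that pairing, while in the real pairing such a wave adds to the residual spread. Neither 610 nor 1987 is therefore a measure of chance for the 12 h wave. Of the 15 ways to pair the 6 libraries, 5 gave at least 3 genes, the real one included, and the highest count in another pairing was 7.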

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

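Tests chosen after the results were seen were the removal of the length and GC trend, the member count at unadjusted p, and summed transcripts for lists, named genes and the 12 h wave. No paired analysis was possible because each time has 1 library. The count of 2 genes with a 24 h wave (limma) became 0 with log2(FPKM + 0.1) and 0 with no filter (25013 genes tested), 9 at a mean of at least 5 FPKM (7406 genes), 1 with quantile normalization, 1 without trend, 17 with robust moderation, 36 with summed transcripts, 1 with the length and GC trend removed, 492 at the smallest permutation p (203 expected by chance) and 98 at adjusted p under 0.1. Ordinary least squares gave 2 other genes. The count ranged from 0 to 2 with 1 time left out. The core clock genes among these numbered 0, 0, 2, 1, 1, 5, 8, 1, 4 and 9 in the same order, 0 by ordinary least squares and 0 to 2 with 1 time left out. Beside those counts of 0, 2215 and 2967 genes were at unadjusted p under 0.05 with log2(FPKM + 0.1) and no filter. Adjusted over the list alone, 14 clock genes became 7 at a mean of at least 5 FPKM, where fewer are tested, and 9 by ordinary least squares, and were 13 to 16 under every other alternative. The 2195 genes at unadjusted p under 0.05 became 1049 without ZT20 and 1444 without ZT16, up to 2173 without ZT4. The 1 list called became 0 with log2(FPKM + 0.1), no filter, quantile normalization, no trend, ordinary least squares and the length and GC trend removed, 2 with robust moderation, 4 with summed transcripts and 9 at unadjusted p, and 0 to 1 with 1 time left out. Those 9 lists became 1 by ordinary least squares, 2 with the length and GC trend removed and 19 with no filter. The 3 genes with a 12 h wave became 1 with no filter, 6 with median-of-ratios factors, 6 with quantile normalization, 5 without trend, 7 with robust moderation, 0 by ordinary least squares (207 at unadjusted p under 0.05 by limma), 7 with summed transcripts and 7 at adjusted p under 0.1. Peak times gave no value with log2(FPKM + 0.1) and no filter, where 0 genes passed. Of 164 named genes, 2 had a peak that moved by over 6 h: Slc7a13 without ZT4 (amplitude 0.104; 0.064 to 0.16 with any 1 time left out) and Slc8a1 with summed transcripts (0.23) and without ZT4 (0.319; 0.036 to 0.342). Neither had an unadjusted p under 0.05 before. Apart from the numbers of genes tested and times fitted, the cause was not tested.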

Other observations

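The tests of the ZT16 library alone, of handling, of the share of glomeruli and vessels, and of the orders and pairings of the libraries were chosen after the results were seen. Further genes with 24 h waves outside the lists appeared with summed transcripts, where 36 genes passed the adjusted threshold (limma). Among them were Igfbp1, an insulin-like growth factor binding protein gene with a peak at ZT4.33 and an amplitude of 1.04, Clpx, a subunit of the mitochondrial protease, at ZT23.3, the nuclear receptor gene Nr2f6 at ZT21.5, Ak4, a mitochondrial adenylate kinase, at ZT13.0, and the collagen genes Col4a3 at ZT1.56 and Col27a1 at ZT16.3. With the most abundant transcript alone their adjusted p lay between 0.068 (Igfbp1, Col4a3) and 0.0986 (Ak4, Col27a1).

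The number of genes with a 24 h wave was set against other orders of the libraries. Of 60 circular orders, 1 gave as many as 2 genes at adjusted p under 0.05 (limma), the real one, and the highest other gave 1. These counts are too small to exclude an accidental order, and the real order gave 0 genes with log2(FPKM + 0.1) and with no filter. With summed transcripts the real order gave 36 genes and any other at most 1. At unadjusted p under 0.05 it gave 2195 genes, against 1928 in the next order, which only exchanges ZT4 and ZT8. For the 12 h wave 5 of 15 pairings gave as many as the 3 genes found, with 7 the highest other, and 15 pairings are too few for a share under 0.05.

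Heat shock chaperones were high at ZT16 while cold-inducible transcripts were low at ZT16 and ZT20. A fault of the ZT16 library alone stays open. Without ZT16 the list was still called, with 6 members in place of 9 (Fisher adjusted p = 0.0249). At ZT20, 12 of 16 heat shock genes were higher than at each of ZT0, ZT4, ZT8 and ZT12, but this is 1 other library, with genes regulated together. The median difference from ZT0 to ZT12 was 0.476 (95% interval 0.254 to 0.57) at ZT20 and 1.132 (0.87 to 1.534) at ZT16. Intervals of medians, here and below, come from 10000 bootstrap draws over the genes of a set within these single libraries. They treat genes regulated together as independent and hold no spread between mice, so they do not give the uncertainty of a time effect. A trend on transcript length or GC content is argued against by the median heat shock difference of ZT16 from the other libraries, which was 1.09 (95% interval 0.746 to 1.335) before and 1.062 (0.73 to 1.318) after its removal, although the list call ended, because 6 members in place of 9 passed while the genes at unadjusted p under 0.05 went from 2195 to 2444. Tissue handling stays open too: immediate early genes stood 0.136 (0.018 to 0.41) above the other libraries at ZT16 in the median, but 0.017 (-0.223 to 0.095) from ZT20. With 1 library per time, a daily change in body temperature may underlie the pattern as well as a difference between mice, and these cannot be told apart here.

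Podocyte, endothelial and stromal markers were high at ZT20. A trend on length or GC content is argued against, since the median difference from ZT0 to ZT12 was 0.635 (95% interval 0.429 to 0.792) before and 0.6 (0.459 to 0.777) after its removal, although the podocyte call ended, because 4 members in place of 5 passed (adjusted p = 0.132) while more genes passed overall. A larger share of glomeruli and vessels in the ZT20 tissue may account for it. At ZT20, 95.7% of 23 markers were higher (all but Cd2ap), but the lists were taken up for their high median there, so this percentage decides nothing. The ZT16 library stood the same way for podocytes (0.619, 95% interval 0.039 to 0.727) and endothelium (0.361, 0.285 to 0.687). For stroma its interval included 0 (0.11, -0.012 to 0.632). Blood markers were higher at ZT16 (0.673) and ZT20 (0.753). One share would scale the FPKM of the markers of a cell type alike. Podocyte, endothelial and stromal markers were pooled here, however, and log2(FPKM + 1) understates the changes of low genes. The SD of the marker differences was 0.349, at the 70.9th percentile of random genes of the same level (median 0.296), so this test leaves a larger share open. A daily rhythm of these cells stays open too: the podocyte list passed the Fisher test with 5 of 7 members (adjusted p = 0.0172) but 9 of 16 alternatives ended that call, with 0 members without ZT20. A single library per time does not separate a rhythm from a difference between mice.

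Short ribosomal and respiratory chain transcripts were low at ZT4. Over 12167 genes the ZT4 deviation rose with transcript length (Spearman rho 0.319, across genes, which are not independent replicates). With the trend removed the ribosomal median went from -0.385 (95% interval -0.486 to -0.225) to -0.219 (-0.278 to -0.131) and the respiratory one from -0.217 (-0.317 to -0.059) to -0.045 (-0.174 to 0.02). A trend between libraries may thus account for part of the ribosomal pattern, and whether it accounts for more than that cannot be told apart from a change at ZT4.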
